A study of Bos taurus with 12 samples.

How the data were processed

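Gene expression was measured in oocytes of Japanese Black cattle with 12 Affymetrix bovine arrays, 3 in each of 4 groups: adult and prepubertal donors at the germinal vesicle (GV) stage and at metaphase II (MII). GV oocytes were taken directly after aspiration from follicles of 2 to 8 mm. MII oocytes were collected after 20 to 22 h of maturation in vitro and chosen by their polar body. Prepubertal donors were heifers aged 9 to 12 months. Each array held RNA from a pool of 50 oocytes freed of cumulus cells, amplified and labelled with biotin. The labels call the 3 pools of a group biological replicates; they name no shared animal or day.

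The values are the log2 signals as deposited. The submitters' processing notes name MAS5 for them; its version is not given in the sources used here. On every array the mean of the linear values without the lowest and highest 2% was 500, so the arrays were not scaled again. Values ran from 0 to 21.83, and the medians of the 12 arrays from 5.64 to 8.30. Of 24128 probe sets, 112 controls were left out. A probe set was kept if its mean over 12 arrays lay above the 40th percentile (5.57 log2 units), which left 14409. Gene symbols came from the array annotation through Entrez identifiers, 99.8% of which matched a table of cattle genes. This gave 13292 probe sets with 1 symbol, 86 with several and 10638 with none, or 9155 genes, 6842 of them kept. No genome coordinates were used.

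Group means were fitted with limma 3.58.1 in R 4.3.3, all 12 arrays in 1 fit with 8 residual degrees of freedom, and variances were moderated with an intensity trend. Comparisons were prepubertal minus adult at each stage, MII minus GV at each age, and the difference between the 2 maturation changes (the interaction). P values were adjusted by Benjamini and Hochberg over the 14409 probe sets, with a threshold of 0.05. The median residual SD of a probe set was 1.87 log2 units, and 720 probe sets would be reached by chance at unadjusted p under 0.05.

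Gene lists were fixed before the data were examined, 26 in all: oocyte-specific and zona pellucida genes, meiotic cell cycle, deadenylation and translational control, cytosolic ribosomal proteins, translation factors, oxidative phosphorylation, mitochondrial biogenesis, glycolysis, fatty acid oxidation, cholesterol synthesis, antioxidants, heat shock proteins, proteasome, spliceosome, chromatin modifiers, histones, DNA repair, apoptosis, cAMP signalling, TGF-beta signalling, gap junction and egg activation, cytoskeleton, endoplasmic reticulum (ER) stress, and markers of cumulus and granulosa cells, of theca and stroma, and of blood cells. They were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene (the one with the highest mean) and at least 5 kept members, and adjusted over the 26 lists of a comparison. A list's size is the mean log2 change of its genes minus that of all other genes. Each list was also tested with a correlation estimated from the arrays, and its genes were also adjusted over the list alone.

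The genes named were chosen by a rule fixed before the data were examined: per comparison, up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold whose values in the 2 groups did not overlap; where fewer than 5 probe sets passed, also the 6 in each direction with the smallest unadjusted p. Members of the oocyte, meiotic, deadenylation and cell type lists could be named with their values in any case. Symbols that are clone or accession names were passed over. The same rule was applied to the fits over 9 and 8 arrays.

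Alternatives fixed before the data were examined were quantile normalization, median centring, no filter and a stricter filter (60th percentile), a pseudocount of 32, only the compared groups, the replicate number as a block, the letter b of some array titles as a covariate, no intensity trend, a threshold of unadjusted p under 0.05 with a 2-fold change, the mean of a gene's probe sets, an estimated correlation, and leaving out each array. Chosen after seeing the data were fits over 9 arrays, without 3 arrays whose oocyte list median lay less than 2 log2 units above the array's median (5 residual degrees of freedom); over 8 arrays, also without MII adult replicate 3, whose highest Spearman correlation was under 0.55 (4 residual degrees of freedom); with array weights; and over the 9 arrays with quantile normalization or median centring. The letter b stood in the titles of GV replicates 1 and 2 of both ages and in no MII title. It was thus partly tied to maturation, and the labels do not explain it. The fits over 9 and 8 arrays did not include it. Whether replicate numbers pair the arrays was checked by correlating deviations from the group means. In the prepubertal groups, GV and MII arrays of the same number correlated at 0.609, 0.149 and 0.306. All 3 lay over 0.1, the bound used, so the numbers were treated as pairs, from the data and not the labels. Both replicate 1 arrays lacked an oocyte profile. Deviations from a mean of 3 arrays cancel out, so these 2 arrays alone could raise all 3 correlations. A shared animal or day was thus not shown. The main fit and the fits over 9 and 8 arrays held no pair term. Replicates 2 and 3 were not told apart, since GV replicate 2 correlated with MII replicate 3 at 0.307 and GV replicate 3 with MII replicate 2 at 0.145. In the other comparisons the correlation was not over 0.1 in every pair.

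The fits were tested on simulated data with the group sizes, the probe set number and a spread like that of the arrays. Over 12 arrays, 3% of probe sets changed by 3 log2 units and 48% of those changed by 6 were recovered for maturation in adults; for the interaction it was 0% and 4%. Over 9 arrays the shares were 6% and 51%, and 2% and 23%. A list shifted by 1 log2 unit was called in 5 of 5 comparisons at the preset correlation and in 3 of 5 with an estimated one. The simulated noise was independent between genes and of the same spread on every array. Genes of a list that vary together were not simulated, so this does not test whether the preset correlation was right. Marker lists on the arrays without an oocyte profile were also compared with genes whose mean over the 9 arrays lay within 0.25 log2 units of each marker's, with bootstrap intervals over the genes of a list. Tables and figures used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.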

Results

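Of the 12 arrays, 9 carried a clear oocyte profile and 3 did not. In the 9 arrays, GDF9 and BMP15, growth factors that oocytes secrete, had mean log2 signals of 13.21 (SD 0.65) and 14.72 (SD 0.27), and the zona pellucida glycoprotein gene ZP2 14.49 (SD 0.68). The median of the 12 oocyte-specific genes lay 5.22 to 8.18 log2 units above the array's median in these 9 arrays. It lay at -0.35 in GV prepubertal replicate 1, 0.75 in MII prepubertal replicate 1 and 0.87 in GV adult replicate 1.

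Both prepubertal replicate 1 arrays carried high signals of genes known from somatic follicle cells. BMP15 read 7.08 at GV and 6.55 at MII, and ZP2 4.99 and 7.98. PTX3 and TNFAIP6, which cumulus cells use to build their expanded matrix, read 14.66 and 13.29 at GV and 14.53 and 13.81 at MII, against means of 5.17 and 4.23 in the 9 arrays. INHA, the inhibin alpha subunit of granulosa cells, read 12.37 and 11.91 against 3.79, and FST, the activin-binding follistatin, 12.53 and 13.72 against 4.88. Compared with the 9 arrays, the mean of these 2 arrays was lower for 10 of 12 oocyte genes (median difference -6.55) and higher for 30 of 35 cumulus and granulosa genes (3.28) and 18 of 19 theca and stroma genes (3.48). Among 16 blood cell genes 10 were higher, by a median of 0.68. The steroidogenic gene STAR was an exception, at 5.11 and 8.74 against 12.27. The median of the cumulus list lay 1.97 and 3.06 above the array's median in the 2 arrays and between -2.01 and 0.51 in the 9 arrays.

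GV adult replicate 1 had low signals of oocyte genes, lower than the mean of the 9 arrays in 11 of 12 cases (median difference -3.50). It was higher for 28 of 35 cumulus genes (2.77), 18 of 19 theca genes (3.77) and 16 of 16 blood genes (3.23). Other genes with low signal in the 9 arrays were higher on it as well: against genes of the same level, in a comparison chosen after seeing the data, the cumulus, theca and blood lists lay at 0.03 (95% interval -1.18 to 0.83), 0.58 (-1.19 to 1.32) and -0.20 (-1.33 to 0.90). For the 2 prepubertal replicate 1 arrays the same values were 2.33 (0.94 to 4.48), 2.11 (0.44 to 3.17) and -0.53 (-1.51 to 0.52). Its highest Spearman correlation with any array was 0.270, and its cre spike-in signal was 21.47, against 17.17 to 20.05 in the 9 arrays.

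**Figure D1:**
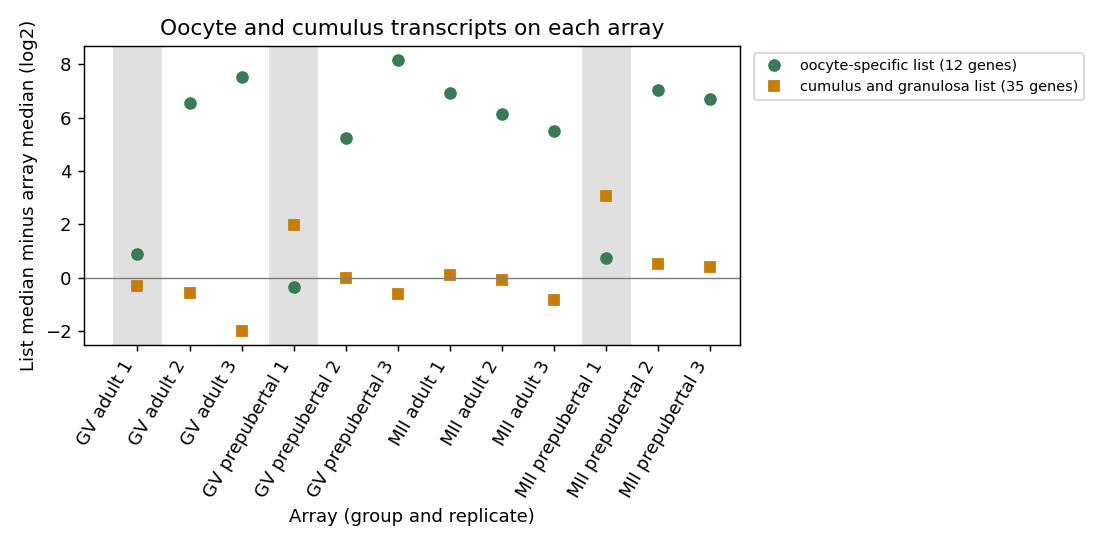
Medians of the oocyte-specific list and of the cumulus and granulosa list on each of the 12 arrays, relative to the array's median log2 signal. The 3 arrays without an oocyte profile are shaded.

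Across the kept probe sets, the first principal component held 30.6% of the variance and the next 2 held 14.9% and 11.1%. The 2 prepubertal replicate 1 arrays correlated best with each other (Spearman 0.664). The closest pair of all was MII prepubertal replicate 2 and MII adult replicate 2 (0.786). MII adult replicate 3, which kept an oocyte profile, reached at most 0.503. GV prepubertal replicate 2 stood apart from the rest of the 9 arrays on the first component, at -75.73 against 26.43 to 117.9. It had the highest array median of the 9 (7.52) and the lowest oocyte list (5.22 above the array's median).

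Before maturation, no gene separated oocytes of prepubertal and adult donors past the threshold. Among the genes with the smallest unadjusted p, prepubertal values were higher for TRMU, a mitochondrial tRNA-modifying enzyme (log2 difference 5.00, SE 1.27), the transcription factor TCF3 (5.09, SE 1.40), the complement regulator CD46 (4.81, SE 1.38), the RNA-binding protein RBM24 (4.61, SE 1.34), CCNI (3.93, SE 1.14) and the sterol carrier NPC2 (3.99, SE 1.19). They were lower for the nucleoside transporter SLC28A3 (-4.83, SE 1.34), the export pump ABCC1 (-4.65, SE 1.54), the integrin ITGB4 (-5.71, SE 1.93), GPS2 (-3.99, SE 1.38), HMGXB4 (-4.61, SE 1.63) and the hyaluronan receptor CD44 (-3.98, SE 1.44). CD44 was dim, at 4.52, 4.33 and 1.3 in prepubertal and 8.65, 6.74 and 6.69 in adult GV arrays. The medians of these arrays ran from 5.65 to 8.30. Its highest value was on GV adult replicate 1, which lacked an oocyte profile. In limma, 0 of 14409 probe sets passed and 362 had unadjusted p under 0.05; over the 9 arrays with an oocyte profile it was 0 and 668.

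At GV, 6 of 26 gene lists had higher values in prepubertal arrays, a call lost with an estimated correlation. Higher values were found for 64 of 67 cytosolic ribosomal genes (mean difference to other genes 1.42, adjusted p = 7.20e-11), 60 of 77 oxidative phosphorylation genes (0.59, adjusted p = 0.00336), 32 of 36 heat shock genes (0.93, adjusted p = 0.00286), 51 of 60 spliceosome genes (0.59, adjusted p = 0.0171), 39 of 47 translation factors (0.66, adjusted p = 0.0264) and 32 of 38 proteasome genes (0.57, adjusted p = 0.0478). All 6 had adjusted p = 0.824 with an estimated correlation. Adjusted over the list alone, 0 genes passed in any of them. These lists moved with the arrays that lacked an oocyte profile, 1 of which was in each group: over the 9 arrays, a fit chosen after seeing the data, 0 lists passed and the differences were -0.22, -0.25, -0.04, -0.23, -0.16 and -0.16.

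After maturation, most genes of respiration and of the ribosome had higher values in prepubertal arrays, in a test that did not hold with an estimated correlation. It was 69 of 77 oxidative phosphorylation genes (1.29, adjusted p = 5.00e-10; adjusted p = 0.789 with an estimated correlation) and 64 of 67 ribosomal genes (1.40, adjusted p = 2.19e-10; adjusted p = 0.818 with an estimated correlation). Over the 9 arrays, with 2 prepubertal and 3 adult arrays at MII, it was 66 of 77 (0.91, adjusted p = 4.13e-06) and 55 of 67 (0.54, adjusted p = 0.000191), the only lists past the threshold there; both had adjusted p = 0.823 with an estimated correlation. The medians of the oxidative phosphorylation list were 10.00 and 10.12 in MII prepubertal replicates 2 and 3 and 9.07, 9.46 and 8.11 in the 3 MII adult arrays. Adjusted over the list alone, 0 genes passed.

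Over all 12 arrays, 7 further lists passed at MII. Prepubertal values were higher for 20 of 23 cumulus and granulosa genes (1.96, adjusted p = 4.04e-05), 10 of 13 theca genes (1.47, adjusted p = 0.0218), 28 of 38 proteasome genes (1.02, adjusted p = 0.000319), 18 of 22 glycolysis genes (1.03, adjusted p = 0.00482) and 38 of 47 translation factors (0.83, adjusted p = 0.00501). They were lower for 10 of 12 oocyte genes (-1.49, adjusted p = 0.0456) and 33 of 47 meiotic genes (-0.83, adjusted p = 0.00968). With an estimated correlation the 9 lists had adjusted p of 0.789 to 0.908. Over the 9 arrays none of these 7 passed. The oocyte and meiotic differences were 0.01 and 0.01 there and the theca difference 0.09, while proteasome (0.66, adjusted p = 0.0861), translation factors (0.56, adjusted p = 0.0635), cumulus (0.75, adjusted p = 0.241) and glycolysis (0.35, adjusted p = 0.428) kept smaller differences of the same direction. Without MII prepubertal replicate 1 alone, the array with high somatic signals, 3 lists passed, all higher: oxidative phosphorylation, ribosomal and proteasome genes.

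**Figure D2:**
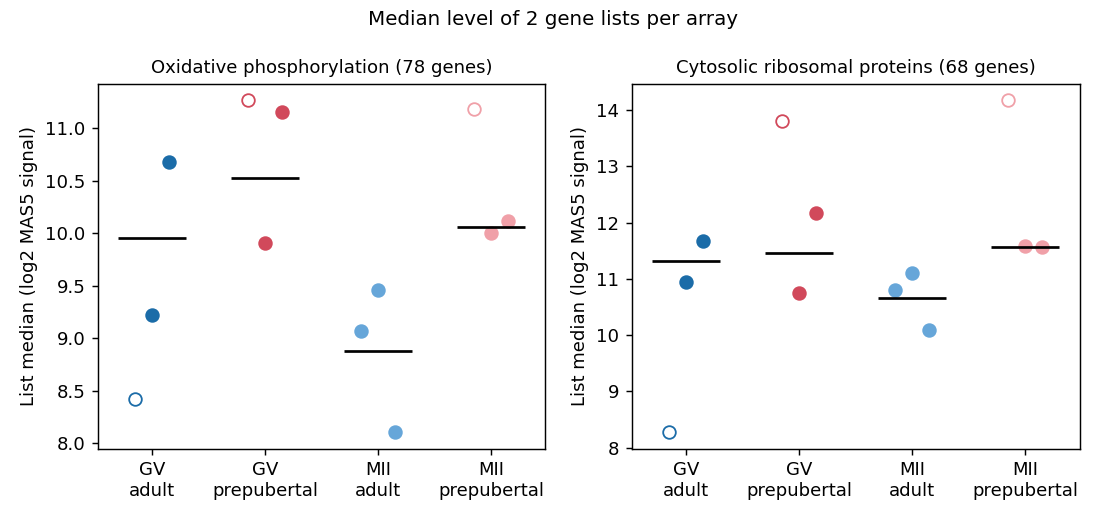
Median log2 signal of the oxidative phosphorylation and cytosolic ribosomal lists on each array. Open circles are the 3 arrays without an oocyte profile, and horizontal bars are means of the other arrays.

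No single gene passed between the ages at MII. The smallest unadjusted p belonged to higher values of the proteasome subunit PSMB4 (4.88, SE 1.32), the dynactin subunit DCTN3 (6.14, SE 1.71), TSTD3 (4.52, SE 1.30), HDDC2 (4.41, SE 1.32), the sialyltransferase ST3GAL4 (6.58, SE 1.97) and HOPX (5.94, SE 1.78). Lower values were read for the lymphoid transcription factor IKZF3 (-5.32, SE 1.68), PRRG4 (-4.34, SE 1.40), the mucin MUC15 (-5.26, SE 1.73), the interferon regulator IRF7 (-4.47, SE 1.51), the myosin heavy chain MYH1 (-5.59, SE 1.98) and BANP (-3.82, SE 1.36). In limma, 0 probe sets passed and 383 had unadjusted p under 0.05; over the 9 arrays it was 0 and 369. There ST3GAL4 read 4.08 and BANP -2.02: MII prepubertal replicate 1 had 14.41 and 5.60, against 7.26 and 11.30 in replicate 2 and 6.56 and 10.69 in replicate 3.

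In adults, 17 probe sets changed with maturation over the 9 arrays with an oocyte profile, a fit chosen after seeing the data. Of these, 7 were higher and 10 lower at MII, and 9 genes met the naming rule. RAD50, a subunit of the MRE11 DNA repair complex, rose by 3.84 (SE 0.61, adjusted p = 0.0215), from a mean of 9.53 (SD 0.07, n = 2) to 13.36 (SD 0.09, n = 3). The ribosomal protein gene RPL38 fell by 3.79 (SE 0.60, adjusted p = 0.0215), the mitochondrial ribosomal gene MRPS6 by 3.72 (SE 0.66, adjusted p = 0.0482), TMA7 by 3.96 (SE 0.61, adjusted p = 0.0215) and the arginyl-tRNA synthetase RARS1 by 3.09 (SE 0.49, adjusted p = 0.0215). NDUFA12, a subunit of respiratory complex I, fell by 3.50 (SE 0.55, adjusted p = 0.0215) and ATP5IF1, an inhibitor of the mitochondrial ATP synthase, by 3.14 (SE 0.54, adjusted p = 0.0393). CNIH4, which helps receptors leave the ER, fell by 3.17 (SE 0.37, adjusted p = 0.00574), from 16.23 (SD 0.17, n = 2) to 13.06 (SD 0.52, n = 3), and the chaperone HSP90AA1 by 2.80 (SE 0.50, adjusted p = 0.0497). Over all 12 arrays, limma called 0 probe sets and 1143 had unadjusted p under 0.05, against 1645 over the 9 arrays. In that fit CNIH4 read -0.57, RPL38 -2.01 and HSP90AA1 -0.26, with values of 8.43, 8.53 and 7.61 in GV adult replicate 1. The 17 calls became 16 with quantile normalization of the 9 arrays (12 in common) and 0 with median centring. Centring moved all changes by the same small amount, CNIH4 to -3.07 and RAD50 to 3.94. Their unadjusted p in limma rose from 3.99e-07 to 0.000677 and from 1.52e-05 to 0.000845, so smaller changes do not account for the lost calls. Over 8 arrays, without MII adult replicate 3 as well, 69 probe sets passed, 26 higher and 43 lower, with all 17 among them.

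**Figure D3:**
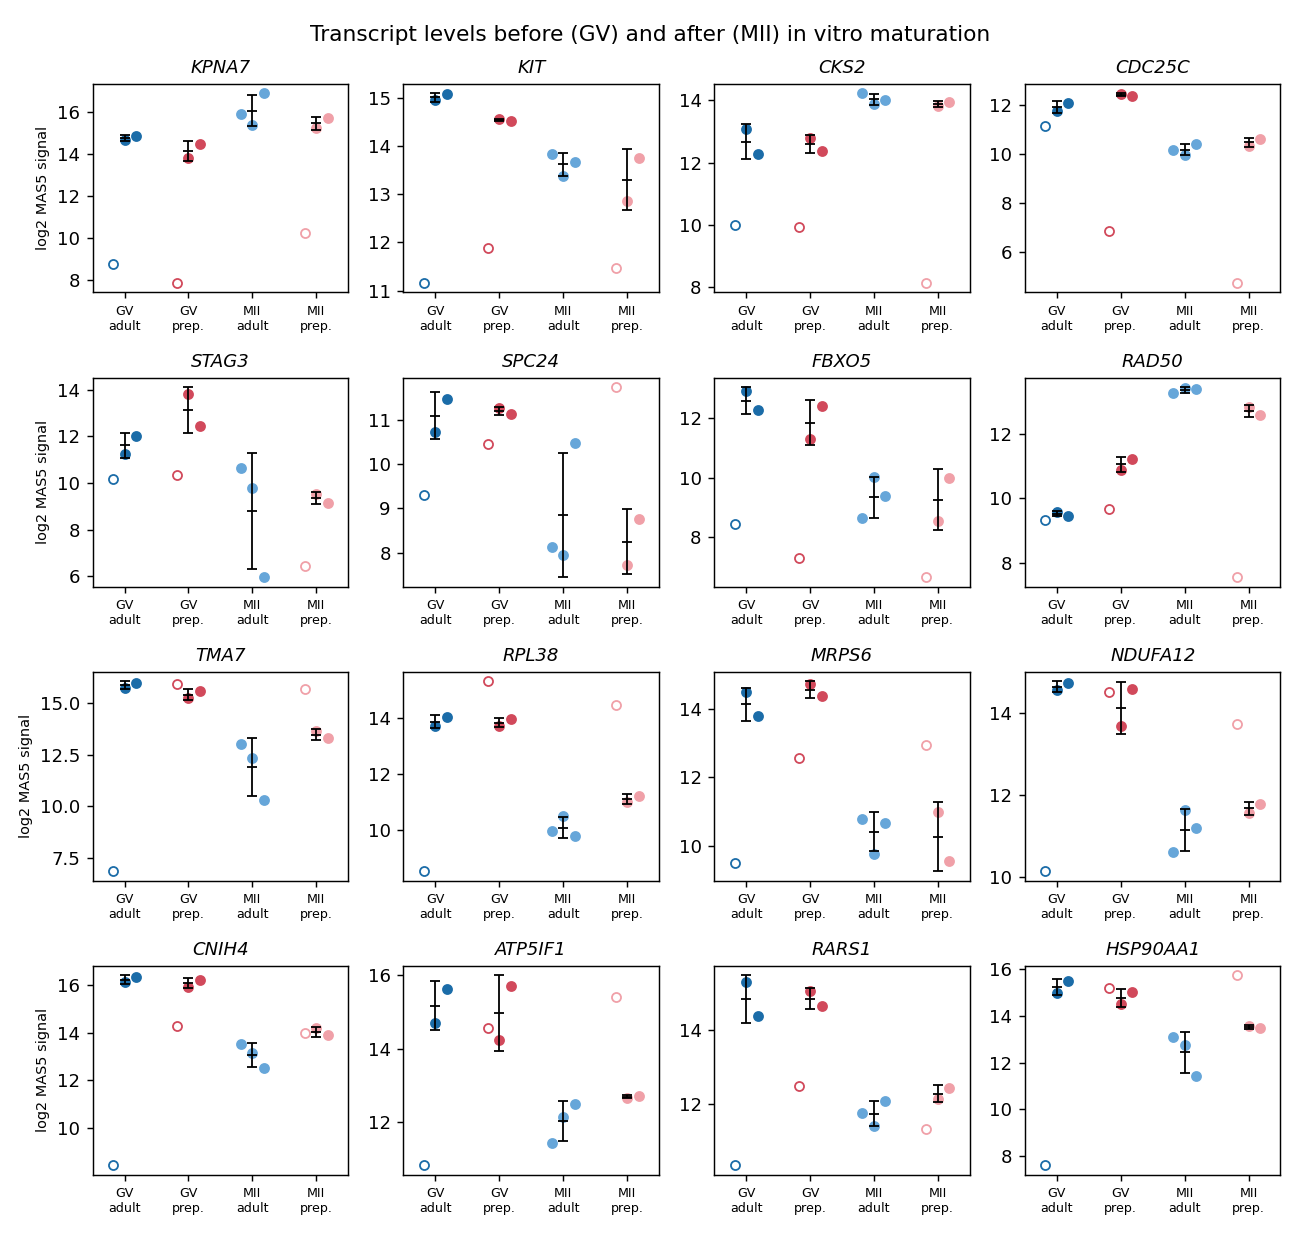
Log2 signals of genes of the oocyte and meiotic lists and of genes called in adults over 9 arrays, by group. Open circles are the 3 arrays without an oocyte profile, and bars are mean and SD over the other arrays.

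The oxidative phosphorylation list fell in adult maturation over the 9 arrays: 59 of 77 genes had lower values (mean difference to other genes -1.29, adjusted p = 7.52e-06; adjusted p = 0.646 with an estimated correlation). The medians of the list overlapped between the stages. They were 9.23 and 10.68 in GV adult replicates 2 and 3, against 9.07, 9.46 and 8.11 in MII adult replicates 1, 2 and 3. Of its genes 2 fell adjusted over all probe sets and 9 adjusted over the list alone. Over all 12 arrays the list read -0.60 (adjusted p = 0.0649), and 3 other lists rose instead: 19 of 23 ER stress genes had higher values (1.51, adjusted p = 0.00476), as had 42 of 60 spliceosome genes (0.89, adjusted p = 0.0178) and 27 of 40 deadenylation genes (1.02, adjusted p = 0.0327). The 3 lists had adjusted p = 0.889 with an estimated correlation. Without GV adult replicate 1 none of the 3 passed, and 1 list passed, with lower values at MII.

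Genes with the smallest unadjusted p in adult maturation over 12 arrays did not pass the threshold. Values were higher at MII for the histone methyltransferase NSD3 (7.39, SE 1.49), the lipid carrier STARD10 (5.73, SE 1.40), the autophagy receptor NBR1 (4.47, SE 1.15), ERBIN (5.40, SE 1.40), the small-RNA processing enzyme DICER1 (5.11, SE 1.38) and the splicing factor U2AF1 (4.35, SE 1.19). They were lower for MAGEF1 (-4.79, SE 1.03), ZNF746 (-6.99, SE 1.57), SLC35F6 (-6.65, SE 1.63), MCRIP1 (-4.85, SE 1.19), ECD (-5.04, SE 1.27) and DYNC2I2 (-4.58, SE 1.27). Over the 9 arrays, the poly(A) polymerase PAPOLA (5.38, SE 1.19), PATL1 (5.10, SE 1.44) and DICER1 (5.25, SE 1.51) rose among 40 deadenylation genes when adjusted over the list alone.

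In prepubertal donors, no probe set passed for maturation over 12 or 9 arrays. Over 8 arrays, a fit chosen after seeing the data, 5 fell: the U3 snoRNP component IMP4 by 5.83 (adjusted p = 0.0487), TMEM185B by 4.32 (adjusted p = 0.0459), MRPS6 by 4.28 (adjusted p = 0.0459), the DNA polymerase epsilon subunit POLE4 by 3.16 (adjusted p = 0.0459) and CNIH4 by 2.04 (adjusted p = 0.0459). Of the 17 probe sets called in adults, 16 had the same sign in prepubertal donors over the 9 arrays, as had 62.5% of all 14409 probe sets, with RAD50 at 1.65, RPL38 at -2.73, NDUFA12 at -2.45, ATP5IF1 at -2.27, RARS1 at -2.57, TMA7 at -1.93 and HSP90AA1 at -1.24. Across 14409 probe sets, which are not independent replicates, the 2 maturation changes correlated at 0.33 (Pearson) over the 9 arrays.

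Over 12 arrays, the smallest unadjusted p in prepubertal maturation belonged to higher values of the Polycomb component PCGF1 (5.39, SE 1.84), ABCF2 (4.61, SE 1.59), the histone demethylase KDM3A (5.07, SE 1.75), TTC4 (3.72, SE 1.29), PPP4R3B (3.37, SE 1.17) and ZMYND11 (3.66, SE 1.29). Values were lower for PPP1R42 (-6.28, SE 1.77), the sodium-proton exchanger SLC9A3 (-5.07, SE 1.49), IRF7 (-5.11, SE 1.51), TMIGD1 (-5.30, SE 1.57), the mitochondrial ribosomal gene MRPL41 (-4.80, SE 1.44) and the ceramide synthase CERS4 (-4.27, SE 1.29). In limma, 0 passed and 492 had unadjusted p under 0.05; in a fit of the 6 prepubertal arrays it was 0 and 543, and with the replicate number as a block in that fit 0 and 1455 (10.1% of probe sets, lowest adjusted p = 0.156). Over the 9 arrays it was 0 and 1007. KDM3A read 2.93 without GV prepubertal replicate 3. The ER stress list rose, with higher values for 16 of 23 genes (1.06, adjusted p = 0.0117; adjusted p = 0.984 with an estimated correlation). With the replicate number as a block, fitted over the 6 prepubertal arrays, 3 lists passed; lists over these arrays without the block were not tested. Over the 9 arrays 0 lists passed, and without GV prepubertal replicate 1 alone 8 did.

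Some oocyte and meiotic genes had maturation values of the same sign at both ages in the 9 arrays, none past the threshold adjusted over all probe sets. KPNA7, an oocyte importin, read 1.31 (SE 0.40) in adults and 1.32 (SE 0.44) in prepubertal donors, and the receptor gene KIT -1.39 (SE 0.40) and -1.25 (SE 0.44). Among meiotic genes, the CDK-binding CKS2 read 1.37 (SE 0.46) and 1.30 (SE 0.50), the phosphatase CDC25C -1.73 (SE 0.71) and -1.94 (SE 0.77), the meiotic cohesin STAG3 -2.82 (SE 1.18) and -3.78 (SE 1.29), the kinetochore gene SPC24 -2.24 (SE 1.03) and -2.95 (SE 1.13), and FBXO5, an inhibitor of the anaphase-promoting complex, -3.25 (SE 0.87) and -2.61 (SE 0.95). These were the 2 of 12 oocyte genes and 5 of 47 meiotic genes with unadjusted p under 0.05 and the same sign at both ages; 0 had opposite signs. All 7 kept the same sign at both ages under other scalings of the 9 arrays, but their p values depended on the scaling. With quantile normalization 6 of the 7 kept unadjusted p under 0.05 at both ages, and with median centring 0. With median centring KIT read -1.28 and -0.44, FBXO5 -3.15 and -1.81 and KPNA7 1.41 and 2.12. Signs matched for 9 of 12, 34 of 47 and 27 of 40 genes of the oocyte, meiotic and deadenylation lists, and for 62.5% of all 14409 probe sets. In adults KIT, ZP2 (-1.26, SE 0.41) and NLRP5, a maternal-effect gene (-3.07, SE 0.93), fell and KPNA7 rose when adjusted over the oocyte list alone. GDF9 read -0.13 (SE 0.53) in adults and -1.35 (SE 0.58) in prepubertal donors, and BMP15 -0.02 (SE 0.34) and 0.27 (SE 0.38).

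At the preset correlation, the respiration and ribosomal lists passed in the interaction over the 9 arrays, a call lost with an estimated correlation. The interaction was positive for 59 of 77 oxidative phosphorylation genes (1.16, adjusted p = 0.00318) and 54 of 67 ribosomal genes (0.76, adjusted p = 0.00349); both had adjusted p = 0.875 with an estimated correlation. Maturation moved the respiration list by -1.29 against other genes in adults and by -0.12 in prepubertal donors. Arrays of the same group lay far apart, with list medians of 9.23 and 10.68 in GV adult replicates 2 and 3. In GV prepubertal replicates 2 and 3 they were 9.91 and 11.15. Over all 12 arrays 0 lists passed, the lowest adjusted p being 0.0624 for theca genes, and the ribosomal difference was -0.02. With quantile normalization of the 9 arrays 1 list passed.

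For single genes the interaction gave 0 calls in limma and 174 at unadjusted p under 0.05 (0 and 441 over the 9 arrays). The smallest unadjusted p belonged to positive values of the complex I subunit NDUFA7 (6.42, SE 2.05), DCTN3 (6.63, SE 2.42), HMGXB4 (6.18, SE 2.31), B3GALT4 (6.05, SE 2.27), the creatine transporter SLC6A8 (5.77, SE 2.22) and RNASEH2A (5.63, SE 2.25); B3GALT4 read 3.88 over the 9 arrays. Negative values were read for the kinase DAPK1 (-6.14, SE 2.05), SLC25A16 (-4.98, SE 1.75), ERBIN (-5.41, SE 1.99), RBM24 (-5.12, SE 1.89), STARD10 (-5.32, SE 1.98) and GMEB1 (-5.22, SE 1.95).

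The other 13 lists passed in none of the 5 comparisons over 12 arrays. Their lowest adjusted p were 0.0627 for chromatin modifiers and 0.0870 for DNA repair, both in adult maturation, 0.174 for antioxidants, 0.294 for cytoskeleton, 0.390 for gap junction and egg activation and 0.450 for cAMP signalling, all 4 at GV, and 0.243 for apoptosis, 0.477 for fatty acid oxidation, 0.569 for mitochondrial biogenesis and 0.569 for TGF-beta signalling in prepubertal maturation. In adult maturation they were 0.478 for cholesterol synthesis, 0.495 for blood cells and 0.551 for histones. Over the 9 arrays, too, none of the 13 passed.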

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

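All tests in this part were chosen after the results were seen. For 2 gene lists the difference between the maturation changes at the 2 ages passed the threshold at the preset correlation, over the 9 arrays with an oocyte profile. The difference was 1.16 log2 units for oxidative phosphorylation (adjusted p = 0.00318) and 0.76 for cytosolic ribosomal proteins (adjusted p = 0.00349), each against all other genes. Both had adjusted p = 0.875 with an estimated correlation. With quantile normalization of the 9 arrays only oxidative phosphorylation passed, and the ribosomal difference was 0.42.

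The prepubertal replicate 1 arrays at GV and MII had low oocyte and high cumulus signals. RNA mostly from somatic follicle cells is a candidate explanation, since the cumulus list lay at least 1.97 above the array's median in both. The oocyte list reached at most 0.75 there, which does not go with a little carry-over beside a main part of oocyte RNA. These arrays were set apart by that same value, so it is no separate test. Failed hybridisation is argued against by the correlation of 0.664 between the 2 arrays, and donor age by an oocyte list at 5.22 or more in the other prepubertal arrays. Whether cumulus cells stayed on the oocytes, other cells were taken or a tube was exchanged stays open.

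GV adult replicate 1 had few oocyte transcripts and shared little with any array. Its highest Spearman correlation was 0.270, which restates this pattern and is no separate test. Its cre and bioB spike-in signals, 21.47 and 15.29, lay above those of every other array. MII adult replicate 3, which kept an oocyte profile, came next at 20.05 and 15.11. All arrays were scaled to the same mean, so bright spike-ins show only that the sample's signal was low beside them. They do not tell weak labelling from failed hybridisation. Weak labelling of the sample RNA may account for the array but was not tested apart. Its somatic and blood genes were above the 9 arrays (medians 2.77 to 3.77), but so were other genes of the same level. Against these the highest of the 3 list medians was 0.58, for theca (95% interval -1.19 to 1.32). No excess of somatic or blood genes was thus seen. The theca interval overlapped that of the prepubertal replicate 1 arrays (0.44 to 3.17). An array with weak sample signal could read like this whatever cells gave the RNA, so this does not decide its source. Degraded RNA was not tested and stays open.

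Oxidative phosphorylation and ribosomal genes had higher values in prepubertal MII arrays. Somatic RNA in MII prepubertal replicate 1 as the whole cause is argued against by adjusted p of 4.13e-06 and 0.000191 without the 3 arrays, and the low correlation of MII adult replicate 3 by 1.12e-05 and 8.32e-05 without that array too. Variation between arrays that the genes of a list share could still give such a difference: with an estimated correlation the adjusted p were 0.823 and 0.823. In simulated data with independent genes, that test called shifts of the sizes seen in 38 of 50 runs for oxidative phosphorylation and 7 of 50 for ribosomal genes. A miss thus decides little for the ribosomal list. For oxidative phosphorylation most runs were called, but fewer than the share set for a miss to count. Genes of a real list may vary together, which these runs did not hold. The miss thus decides for neither list. The adjusted p without the left-out arrays rested on the preset correlation, so shared variation would weaken those arguments too. Lesser somatic carry-over in replicates 2 and 3, whose cumulus list lay 0.51 and 0.40 above the array's median against 0.10, -0.07 and -0.85 in the MII adult arrays, was not tested and stays open, as does donor age, with 2 prepubertal arrays left at MII.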

How the results depend on the processing

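The 12 arrays included 3 without an oocyte profile and had a median residual SD of 1.87 log2 units. In simulated data with a like spread, at most 4% of probe sets changed by 3 log2 units were recovered over 12 arrays. How far the 3 arrays held down the calls was not tested apart. The replicate number as a block was fitted over the 6 arrays of a comparison, and over 12 for the interaction. In adult maturation it gave 7 probe sets, against 0 over these 6 arrays without it. In prepubertal maturation it gave 3 lists, against 1 over 12 arrays; lists over the 6 arrays without the block were not tested, so the block was not told apart from leaving out the adult arrays. It changed no other count of calls by over 1.5 times. At unadjusted p under 0.05 the block moved 229 to 617 (age at GV) and 543 to 1455 (maturation in prepubertal donors) over the 6 arrays, and 174 to 274 (interaction). Same-numbered arrays did not correlate in every pair in adult maturation (-0.11, 0.02 and -0.08), between the ages at GV (0.38, -0.02 and 0.38) or at MII (-0.09, 0.10 and -0.07). For single probe sets, leaving out 1 array gave 0 to 0 calls in all 5 comparisons, and quantile normalization, median centring, the 2 filters, the pseudocount, the letter b, no trend and only the compared groups gave 0 as well. Unadjusted p under 0.05 with a 2-fold change gave 362 (age at GV), 383 (age at MII), 1143 (maturation in adults), 492 (maturation in prepubertal donors) and 174 (interaction). Of the 60 named results for single genes over 12 arrays none changed sign under any alternative, and in 14 cases a gene passed the threshold under one. These genes were chosen by their small p in the same arrays. The filters, the trend, the threshold, only the compared groups and leaving out an array of another group cannot change such a difference. The kept signs were thus largely fixed in advance and are no check of these genes. Of the list differences under an alternative, 335 kept their direction and side of the threshold, 149 kept the direction but no longer passed, 18 newly passed, and 70 turned sign. Except where stated, the cause was not tested.

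The alternatives chosen after seeing the data gave for single probe sets: array weights 1 at GV, 1 at MII, 96 for maturation in adults and 5 in prepubertal donors; 9 arrays 17 in adults, or 16 with quantile normalization; 8 arrays 69 in adults and 5 in prepubertal donors.

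Lists past the threshold between the ages at GV were 6, all higher, and 1 with array weights, a lower one, 2 with median centring, 3 with the stricter filter, 0 with an estimated correlation, and 0 over 9 or 8 arrays, with an estimated correlation or, over 9, quantile normalization or median centring too. Leaving out 1 array gave 3 to 8, with 3 without GV adult replicate 1 (1 higher, 2 lower), 3 without GV prepubertal replicate 1 (2 higher, 1 lower) and 4 without GV prepubertal replicate 3 (2 higher, 2 lower). At MII they were 9 (7 higher, 2 lower), and 4 with array weights, 0 with an estimated correlation, 2 over 9 arrays, 0 with an estimated correlation, 2 with median centring, 3 with quantile normalization, 2 over 8 arrays and 0 with an estimated correlation; leaving out 1 array gave 3 to 9, the 3, all higher, without MII prepubertal replicate 1. The lists past in fits over 9 or 8 arrays or with array weights were all higher. For maturation in adults they were 3, all higher, and 7 with the mean of a gene's probe sets (5 higher, 2 lower), 8 without a filter, 1 with quantile normalization, 0 with the stricter filter, 0 with an estimated correlation, 1 with array weights, 1 over 9 arrays under each of the 3 scalings and 1 over 8 arrays, each a lower one, and 0 with an estimated correlation over either; leaving out 1 array gave 1 to 8, with 1, lower, without GV adult replicate 1, 6 without GV adult replicate 2 (1 lower) and 8 without GV adult replicate 3 (1 lower). For maturation in prepubertal donors 1 became 4 without a filter and 0 with array weights, an estimated correlation, the mean of probe sets, quantile normalization, median centring, the stricter filter and in all fits over 9 or 8 arrays; leaving out 1 array gave 0 to 8, with 0 without GV prepubertal replicate 2, 4 without GV prepubertal replicate 3, 8 (2 lower) without GV prepubertal replicate 1 and 5 without MII prepubertal replicate 2 or 3. Without an adult GV array it was 3, 2 and 3. For the interaction 0 became 1 with median centring, 2 over 9 arrays, 2 with median centring, 1 with quantile normalization and 2 over 8 arrays; leaving out 1 array gave 0 to 5, with 5 without GV adult replicate 3 (3 lower), 5 without GV prepubertal replicate 1 (2 lower), 4 without GV adult replicate 1, 4 without MII prepubertal replicate 3 (1 lower), 3 without MII prepubertal replicate 2, 2 without GV adult replicate 2 (1 lower), and 1 without GV prepubertal replicate 3, MII adult replicate 3 or MII prepubertal replicate 1 (the last lower).

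List differences that turned sign were, between the ages at GV over 9 and over 8 arrays, ribosomal -0.22, oxidative phosphorylation -0.25, heat shock -0.0403, spliceosome -0.23, translation factors -0.16 and proteasome -0.16. An estimated correlation or median centring of the 9 arrays leaves a list's difference to the other genes as it is, so these were no further checks of the sign. With quantile normalization of the 9 arrays, oxidative phosphorylation was -0.18, spliceosome -0.10, proteasome -0.0366 and translation factors -0.0148. Array weights gave -0.0316 for oxidative phosphorylation, -0.0944 for heat shock and -0.11 for spliceosome. Leaving out 1 array gave -0.14 to 1.49 for heat shock, -0.10 to 1.28 for oxidative phosphorylation, -0.0174 to 1.05 for proteasome and -0.10 to 0.94 for spliceosome, each lowest value without GV adult replicate 1. At MII the oocyte list ran from -2.25 to 0.00714 and the meiotic list from -1.29 to 0.00973, the highest without MII prepubertal replicate 1; they were 0.00714 and 0.00973 over 9 arrays and 0.11 and 0.12 over 8. Oxidative phosphorylation in adult maturation ran from -1.29 without GV adult replicate 1 to 0.10 without GV adult replicate 3. The ribosomal interaction (-0.02) ran from -0.88 to 1.02, the highest without GV adult replicate 1, and was 0.10 with the mean of probe sets, 0.0396 with the stricter filter, 0.32 with array weights, 0.76 over 9 arrays (0.76 with median centring too, which cannot change it), 0.42 with quantile normalization and 0.66 over 8.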

Other observations

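The tests in this part were chosen after the results were seen. Each comparison was repeated with the arrays of its 2 groups dealt out in every other way, 10 splits with the real one, which are too few for a share under 0.05. For single probe sets the real count was 0, which every split reaches, 10 of 10 in each comparison, so this decides nothing; the highest other was 1 at GV between the ages, 0 at MII, 1 for maturation in adults and 1 in prepubertal donors. For gene lists, the real 6 at GV was reached in 6 splits (highest other 9), the real 9 at MII in 3 (highest other 9), the real 3 of adult maturation in 10 (highest other 11) and the real 1 of prepubertal maturation in 7 (highest other 8). Among the 4 splits that part all 3 prepubertal pairs of equal number, the highest other was 5 lists. At MII and in adult maturation every other split passed at least 3 lists, over 12 arrays and at the preset correlation. At GV the other splits passed 0 to 9. Lists thus passed in groupings other than the real ones. A low adjusted p at the preset correlation therefore does not by itself mark a difference between the groups. For the interaction the real counts of 0 probe sets and 0 lists are likewise reached by all 100 of 100 splits and decide nothing (highest other 1 and 12).

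Some splits held many more probe sets at unadjusted p under 0.05 than the real ones, which points to a structure of the samples. At GV between the ages the real count was 362 and the highest other 3221. That split set GV prepubertal replicates 1 and 2 and GV adult replicate 1 against the rest. In prepubertal maturation the counts were 492 and 2687, the latter in a split that does not part all 3 pairs. It set GV prepubertal replicates 1 and 2 and MII prepubertal replicate 1 against the rest. Both splits put GV prepubertal replicate 2 beside arrays without an oocyte profile. In the GV split these arrays also all bore the unexplained letter b in their titles, as did GV adult replicate 2 on the other side. In the prepubertal split MII prepubertal replicate 1 did not bear it. The letter and the profile were not told apart. In the interaction the counts were 174 and 2967. Among the 4 splits that part all 3 prepubertal pairs, the real 492 was the largest (highest other 313). In adult maturation the real 1143 was the largest of 10 splits (highest other 1130), and at MII between the ages it was 383 against 670.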
